A study of Mus musculus with 4 samples.

How the data were processed

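RNA sequencing libraries of total RNA from mouse embryonic stem cells of the 129/Ola strain were studied in 2 genotypes, wild type and Chd2 mutant on both alleles. The sample titles call the mutant Chd2KO, while the header of the deposited values calls it Chd2mut/mut. Embryonic stem cells are pluripotent cells that can be grown in culture. Chd2 encodes an ATP-dependent chromatin remodeler of the chromodomain helicase DNA-binding family. Per the labels, each genotype had 2 libraries, marked as lot 1 and lot 2, made with the NEBNext Ultra RNA library kit from cells grown on gelatin in medium with serum and leukemia inhibitory factor. Nothing in the labels says whether the lots were separate cultures, or whether a lot number marks a day or batch shared by the genotypes, so the spread behind the authors' q-values may be technical.

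The authors deposited 1 table with 1 FPKM value per gene and genotype. FPKM counts sequenced fragments scaled for transcript length and for the number of fragments mapped in a library. Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.1.0 and Cufflinks were used with the mouse build mm9. The Cufflinks version and the gene annotation are not given in the sources used here. The values for the separate lots are not analysed here, so the FPKM of a genotype is the authors' own value over its libraries and carries no standard deviation. The depth of the libraries is unknown, and no counting interval can be given. Per the file headers, the authors also deposited a log2 fold change of mutant over wild type, a q-value and a yes or no call for each gene. The test behind the q-value is not given in the sources used here. All 81 genes with a call of yes have a q-value under 0.05 in the authors' deposited table, and no other gene has one. The fold change is the plain ratio of the FPKM values, without a pseudocount, and is infinite where 1 genotype is listed at 0. It differs from that ratio by more than 0.001 for Actr3, Sept7 and Tnpo1, none of them called, and is given as 0 for Nono, which is listed at 0 in wild type and at 241.3 FPKM in the mutant. A value of 0 can therefore be a failed estimate.

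The table lists 23309 gene names without repeats. Of these rows, 104 hold several symbols joined by commas. Transcripts such as small nucleolar RNAs and microRNAs are listed although FPKM is unstable for short transcripts. The 10766 genes with a mean FPKM over the genotypes of at least 1 were kept for the description of changes. For them the change was computed as the difference of log2(FPKM + 1), mutant minus wild type. This scale understates the change of genes near 1 FPKM, and folds quoted for single genes are plain ratios of the deposited FPKM values.

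The design fixed before the data were examined was a limma fit with 2 libraries against 2 and camera tests of gene lists. Neither can be run on 1 value per genotype. Significance of single genes is therefore that of the authors' deposited table. Gene lists are described by the number of called members and by their median change. The percentile of that median was taken among 10000 random lists of the same size drawn from the same 20 bins of expression. This percentile describes these pooled values only. It treats genes as independent and is not a test between conditions. Lists with fewer than 5 genes kept got no percentile. Enrichment of calls in a list was tested with a one-sided Fisher's exact test against the 11276 genes with a q-value under 1, with Benjamini-Hochberg adjustment over 35 lists. The table gives q-values and no p-values, so counts adjusted over a list alone cannot be given.

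The 36 lists, fixed at the same time, cover pluripotency and lineage genes, chromatin regulators, signalling targets, cell cycle and metabolism, markers of other cell types and RNA quality. Named genes followed a rule fixed at the same time. It takes Chd2, then the 12 largest changes in each direction among genes past the threshold, leaving out gene models and symbols that begin with Mir or Snor. The authors' call stands in for the threshold of the fit that could not be run. The rule also takes, for a table without values per library, the 12 largest differences of log2(FPKM + 1) in each direction without a test, with the same symbols left out and other small RNAs kept, and up to 4 members of each list. Genes named outside this rule are said to be chosen after their values were seen.

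Chromosomes, gene order, transcript length and GC content came from annotation of GRCm38 (RefSeq and GENCODE M21), matched by symbol. Length and GC content are those of the longest annotated transcript of a gene, which need not be the one expressed. A chromosome was found for 99.5% of the genes kept, and length and GC content for 99.3%. This is another build than the authors used, so no coordinates are given. The percentile and neighbour statistics were tested on simulated data. A shift of 0.2 in 30 genes was found in 100% of 40 simulated runs over 10766 genes, a shift of 0.1 in 67.5%, and no shift in 5%. The simulated genes varied independently, so these rates need not hold for lists of genes that vary together. Their spread followed a set formula of the mean FPKM rather than the spread of the data, and no trend with level was simulated. The rates may therefore differ for lists of abundant or weakly expressed genes. The neighbour statistic was tested only on 2000 genes with 40 calls and 10 planted pairs, a denser setting than that of the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives tried were another pseudocount, other filters on low values, quantile normalization, a median change set to 0 and stricter call thresholds.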

Results

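RNA sequencing was carried out on wild-type and Chd2 mutant mouse embryonic stem cells, with 2 libraries per genotype, to ask how mutation of both Chd2 alleles alters RNA levels in undifferentiated cells. The data analysed hold 1 FPKM value per gene and genotype, so the values below have no replicate error of their own, and each statement of significance rests on the q-value of the authors' deposited table. The summed FPKM was 806390 in wild type and 809413 in the mutant. Of 23309 genes listed, 10766 had a mean of at least 1 FPKM and 6120 were at 0 in both genotypes. Over the genes kept, log2(FPKM + 1) of the genotypes correlated across genes with a Pearson r of 0.979, and the median change was -0.0012 on the log2 scale.

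Chd2 itself was lower in the mutant. Its level was 10.2 FPKM in wild type and 5.69 FPKM in the mutant, which is 55.9% of the wild-type level. The authors' deposited table gives it a log2 fold change of -0.84 with a q-value of 0.0103, the smallest q-value in the table. The transcript was thus still detected in the mutant, and no value for separate exons or alleles was analysed here. None of the other 7 members of the CHD family with a mean of at least 1 FPKM was called. The nearest relative, Chd1, was at 16.7 FPKM in wild type and 18.9 FPKM in the mutant, Chd4, the core ATPase of the NuRD complex, at 121 and 107 FPKM, and Chd1l at 16.97 and 14.3 FPKM.

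Across the transcriptome few genes differed between the genotypes, and more of them were lower than higher in the mutant. The authors' deposited table called 81 genes, of which 29 were higher and 52 were lower, or 64.2% of calls lower. They make up 0.718% of the 11276 genes with a q-value under 1. The median change of the genes that rose was 1.69-fold, and that of the genes that fell was 1.93-fold. Only 4 of the genes that rose changed by at least 2-fold, against 24 of those that fell. The median level of the called genes was 7.61 FPKM, as the mean of the genotypes. Of the calls, 50 had a mean of at least 5 FPKM. In the authors' deposited table q-values of called genes ran from 0.0103, shared by 55 genes, to 0.0487.

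**Figure D1:**
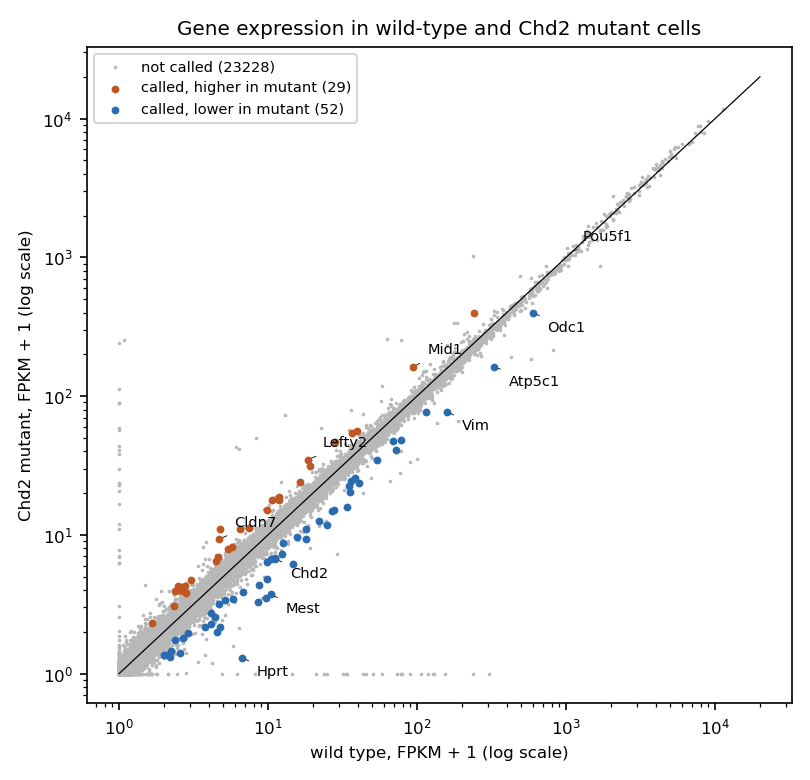
Expression of each gene in wild type (x axis) and Chd2 mutant cells (y axis) as FPKM + 1 on log scales, 1 point per gene, with the 29 genes called higher in orange, the 52 called lower in blue and the line of equal expression in black. Most points lie along the line, and Hprt, Mest and Vim are among the genes below it.

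Among genes that rose, Mia, which encodes a secreted protein first described in melanoma cells, had the largest change. It rose 2.67-fold from 3.76 to 10.0 FPKM. Cldn7, a claudin of tight junctions, rose 2.24-fold from 3.69 to 8.28 FPKM. Crb3, which encodes an apical polarity protein, rose 1.83-fold from 5.48 to 10.0 FPKM. Lefty2, which encodes an inhibitor of Nodal signalling, rose 1.93-fold from 17.4 to 33.7 FPKM and was the most abundant of the 12 genes with the largest increases. Gpc3, a heparan sulfate proteoglycan, rose 1.83-fold to 3.75 FPKM, and the iron exporter Slc40a1 rose 1.96-fold to 3.24 FPKM. The transcriptional repressor Bcl6b rose 2.16-fold to 2.93 FPKM and Miip rose 2.22-fold to 3.304 FPKM. Dpysl5 rose 1.85-fold, Tmem30b 1.80-fold, C2cd5 1.75-fold and the actin-binding Ablim1 1.95-fold. In the authors' deposited table the q-values of these 12 genes ranged from 0.0103 to 0.0487.

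Among genes that fell, Hprt, the purine salvage enzyme encoded on the X chromosome, had the largest change. It dropped 18.9-fold, from 5.68 FPKM in wild type to 0.301 FPKM in the mutant. The labels do not say how the wild-type and mutant lines are related. A difference at Hprt between the lines unrelated to Chd2 therefore stays open as untested. Mest, an imprinted gene, fell 3.47-fold from 9.42 to 2.72 FPKM. Pttg1, which encodes securin, the inhibitor of sister chromatid separation, fell 2.66-fold from 13.8 to 5.19 FPKM. Arl14epl fell 3.46-fold to 2.49 FPKM and Fmr1nb fell 3.297-fold to 2.28 FPKM. The tetraspanin gene Cd37 fell 3.25-fold to 1.16 FPKM, and Ceacam20, of the carcinoembryonic antigen family, fell 3.56-fold to 0.996 FPKM. The remaining genes of this group were below 1.6 FPKM in wild type. They were Rcsd1, which fell 3.84-fold, the bicarbonate transporter Slc4a5, which fell 3.83-fold, the GABA transaminase gene Abat, which fell 3.02-fold, the Y-linked Usp9y, which fell 2.75-fold, and Nlrp9b, which fell 2.66-fold. In the authors' deposited table the q-values of these 12 genes were between 0.0103 and 0.0256. Abundant genes that fell included Vim, Atp5c1 and Stmn2, described with their lists below.

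**Figure D2:**
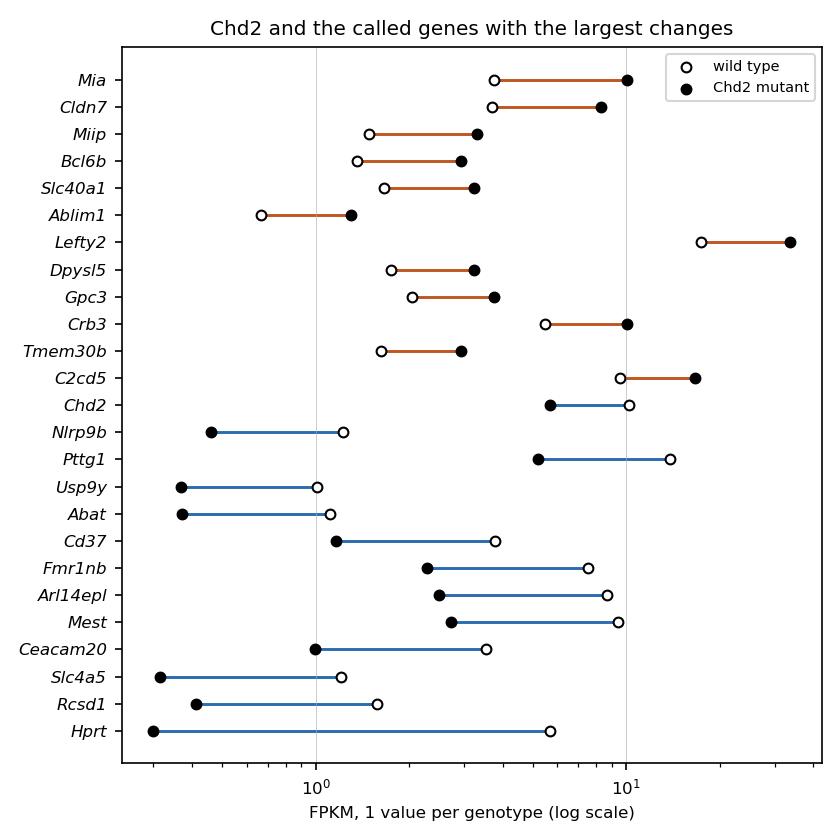
FPKM on a log scale (x axis) of Chd2 and of the 12 called genes with the largest increase and the 12 with the largest decrease (y axis), with open circles for wild type and filled circles for the mutant, 1 value per genotype without error bars. Orange lines mark genes higher in the mutant and blue lines genes lower in it, with Hprt showing the widest gap.

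The largest differences without regard to a call were mostly in short or poorly estimated transcripts. Of 99 genes kept with a change of at least 1 on the log2(FPKM + 1) scale, 13 were called. Small RNA genes with symbols that begin with Mir, Snor or Scarna made up 69 of the 99. Nono was listed at 0 in wild type and at 241.3 FPKM in the mutant. The ribosomal protein gene Rpl26 was at 0.0795 FPKM in wild type and 254 FPKM in the mutant. The authors' deposited table gives these 2 genes q-values of 1 and 0.959. Scarna2, Scarna17 and AF357399 were listed at 128, 117 and 19.9 FPKM in wild type and at 0 in the mutant. Further uncalled genes selected by size were Hist1h2af (0.494 and 3.36 FPKM in wild type and mutant), Rsc1a1 (0.916 and 2.92 FPKM), Tagln (1.15 and 2.97 FPKM), Tusc1 (0.452 and 1.65 FPKM), Nupr1 (2.78 and 5.64 FPKM) and Ybx2 (2.38 and 4.92 FPKM). On the lower side these were Pisd-ps3 (4.80 and 0.567 FPKM), Hist1h2ak (3.20 and 0.184 FPKM), Rpph1 (5.33 and 1.13 FPKM) and Insl3 (2.36 and 0.203 FPKM). Mid1, which encodes a microtubule-associated ubiquitin ligase, was chosen by size and also called. It rose 1.74-fold from 92.8 to 161 FPKM.

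Pluripotency genes were highly expressed in both genotypes, and none of the 33 naive pluripotency genes kept was called. Pou5f1, chosen after its values were seen, was at 1032 FPKM in wild type and 1071 FPKM in the mutant. Nanog was at 114 and 150 FPKM, Sox2 at 178 and 222 FPKM, Tet1 at 12.2 and 15.5 FPKM, and Nr0b1 at 125 and 96.5 FPKM. The median change of the list was 0.04 on the log2 scale, with 19 members above 0 and 14 below, at percentile 99.7 of random lists matched on expression, whose own median was -0.04.

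Genes of the primed and formative epiblast, the state that follows naive pluripotency, had a median change of 0.22, above every one of the 10000 matched random lists. Of 18 genes kept, 2 were called, both higher, and 13 lay above 0. Lefty2 rose as given above, and Cldn6 rose 1.505-fold from 35.6 to 53.5 FPKM. The uncalled Otx2 was at 4.93 FPKM in wild type and 7.59 FPKM in the mutant, and Zic2 at 1.42 and 2.46 FPKM. Other members lay below 0, among them Lef1 at 4.06 and 2.72 FPKM and Dnmt3a at 7.05 and 5.64 FPKM, both picked for this list after their values were seen. The enrichment of calls in the list had a one-sided Fisher's exact p of 0.0072, which was 0.253 after adjustment over 35 lists, and no list passed that adjustment.

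Developmental regulators were mostly silent in both genotypes. None of the 39 Hox genes reached 1 FPKM in either genotype, with a highest value of 0.347 FPKM in wild type and 0.724 FPKM in the mutant. Of 149 developmental transcription factors chosen as typical bivalent genes, 20 reached 1 FPKM in wild type and 22 in the mutant. None of the 21 kept was called, and their median change was -0.05, at percentile 5.92, while their mean change was above 0. The largest uncalled differences in this list were those of Tlx3 (0.604 and 1.56 FPKM in wild type and mutant), Phox2a (1.52 and 2.71 FPKM), Neurog3 (4.69 and 2.865 FPKM) and Pax6 (1.68 and 2.42 FPKM).

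Lineage lists held few calls. In the neuroectoderm list Stmn2, which encodes a microtubule-destabilising protein of neurons, fell 1.79-fold from 71.2 to 39.8 FPKM. It was the 1 call among 11 genes kept, whose median change was -0.05, at percentile 19.13. The mesoderm list had no call among 12 genes kept and a median of 0.19, at percentile 99.8, and at 67.88 without the filter. Its members with the largest differences were Tagln, given above, Meox1 (2.445 and 1.24 FPKM), Etv2 (2.77 and 3.76 FPKM) and Evx1 (1.25 and 1.78 FPKM). The primitive and visceral endoderm list had no call among 13 genes kept and a median of 0.17, at percentile 99.98, with Apoe at 327 and 412 FPKM and Lamb1 at 7.77 and 9.86 FPKM. Without the filter on low values this list lay at percentile 57.17. Of its 20 members with a mean under 1 FPKM, 13 were lower and 6 higher in the mutant. No gene was called in the definitive endoderm list (median 0.05, percentile 66.2) or the trophoblast list (median -0.05, percentile 12.4). The germ cell list had no call and a median of -0.07, at percentile 2.85, with Mael at 4.64 and 2.68 FPKM. Of 34 genes of the 2-cell-like state 6 were kept, with a median of -0.12, at percentile 7.77. Pramel6, expressed in the early embryo, was the 1 called and fell 2.44-fold from 3.12 to 1.28 FPKM. Neuronal function genes had no call and a median of 0.04, at percentile 55.7.

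The fixed lists of chromatin regulators held no call apart from Chd2. Outside these lists, Sfmbt2, which encodes a Polycomb group protein and was chosen after its values were seen, fell 1.82-fold from 11.4 to 6.26 FPKM. The 21 genes kept for histone H3.3 and its chaperones had a median change of -0.06, at percentile 18.4, with H3f3b, which encodes H3.3, at 323 and 280 FPKM. The Polycomb complexes (29 genes, median 0.01, percentile 85.7), the enzymes of H3K4 and H3K27 methylation (26 genes, median 0.01, percentile 67.0) and the other chromatin remodelers (39 genes, median -0.01, percentile 77.5) lay within the central 95% of random lists. The CHD family itself, Chd2 included, had a median of 0.03, at percentile 66.4, with a mean below 0, and a median of -0.18, at percentile 1.91, among genes with a mean of at least 5 FPKM. The H3.3 list lay at percentile 1.57 once the trend on GC content and transcript length was removed. The DNA methylation list had no call, a median of -0.12 and percentile 0.43, with Gadd45a at 22.03 and 16.9 FPKM, Tet1 as given above and Zfp57 at 155 and 132 FPKM. Of 62 replication-dependent histone genes listed, 9 were kept, with a median of -0.06 and percentile 9.43. The fixed list of imprinted genes had Mest as its 1 call among 29 kept and a median of 0.03, at percentile 76.3, with a mean below 0. The uncalled imprinted Nnat was at 2.81 and 0.779 FPKM, Slc38a4 at 38.7 and 27.6 FPKM and Slc22a18 at 2.59 and 4.57 FPKM.

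Lists of growth and metabolism held Atp5c1 and Hprt as calls. Atp5c1, the gamma subunit of ATP synthase, fell 2.02-fold from 327 to 162 FPKM. The 69 oxidative phosphorylation genes kept had a median change of -0.09, at percentile 5.17, and at 35.5 once the trend on GC content and transcript length was removed, with Uqcrc1 at 264 and 202 FPKM and Atp5a1 at 728 and 871 FPKM. The 39 S phase genes had a median of -0.12, at percentile 0.11, and 33 of them lay below 0, such as Ccne1, which encodes cyclin E1, at 253 and 198 FPKM. The 44 genes of G2 and M phase had a median of -0.04, at percentile 35.3. The 76 ribosomal protein genes had a median of 0.10, above every one of the 10000 random lists, and 66 lay above 0. Rpl37a was at 2071 and 2778 FPKM and Rpl39 at 3991 and 4730 FPKM. The p53 targets had a median of 0.09, at percentile 99.8, with Dcxr at 9.61 and 13.8 FPKM and Perp at 15.9 and 20.8 FPKM. Of the 34 p53 targets kept, 23 lay above 0 and 11 below, among the latter Gadd45a at 22.03 and 16.9 FPKM. Glycolysis and hypoxia genes (median -0.04, percentile 30.6), cholesterol synthesis genes (median -0.03, percentile 26.1) and stress and unfolded protein response genes (median -0.08, percentile 6.73) had no call and lay within the central 95%. Of the housekeeping genes, Hprt was the 1 called, and the 26 had a median of -0.08, at percentile 11.4, with Actb at 1386 and 1153 FPKM.

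Targets of signalling pathways showed 1 call, Lefty2 in the TGF-beta and BMP list. That list had a median of -0.07, at percentile 3.20, with 14 of 21 genes below 0. Lefty1 was at 27.7 and 39.6 FPKM and Inhbb at 3.53 and 2.19 FPKM. The LIF and STAT3 targets (median -0.05, percentile 13.3, Socs3 at 34.9 and 28.2 FPKM), the FGF and MAPK targets (median 0.02, percentile 73.3, Spry1 at 6.99 and 8.50 FPKM) and the WNT targets (median -0.05, percentile 14.8, Apcdd1 at 2.58 and 1.78 FPKM) had no call.

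Markers of other cell types lay on either side of 0. In the fibroblast and extracellular matrix list Vim, which encodes the intermediate filament vimentin, fell 2.07-fold from 158 to 76.3 FPKM. The 14 genes kept had a median of -0.08, at percentile 6.03, and at 0.05 among genes with a mean of at least 5 FPKM, and the uncalled Fn1 was at 31.8 and 44.1 FPKM. The blood and endothelium list kept 6 genes with no call and a median of 0.22, at percentile 99.4, with Tek at 2.31 and 3.45 FPKM. The RNA quality list kept 8 nuclear noncoding transcripts with a median of 0.15, at percentile 99.2, and a mean below 0 because of Rpph1. That list lay on the same side as the naive pluripotency, primed epiblast, mesoderm, primitive endoderm, blood and endothelium, ribosomal protein and p53 lists. In all, 10 of 35 lists lay outside the central 95% of random lists, against 1.75 given by chance for independent genes. The naive pluripotency, primed epiblast, p53, ribosomal protein and S phase lists lay outside under every setting that could be run, and the mesoderm, primitive endoderm, blood, DNA methylation and RNA quality lists did not. With 1 value per genotype, how far such medians vary between libraries of 1 genotype is unknown.

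**Figure D3:**
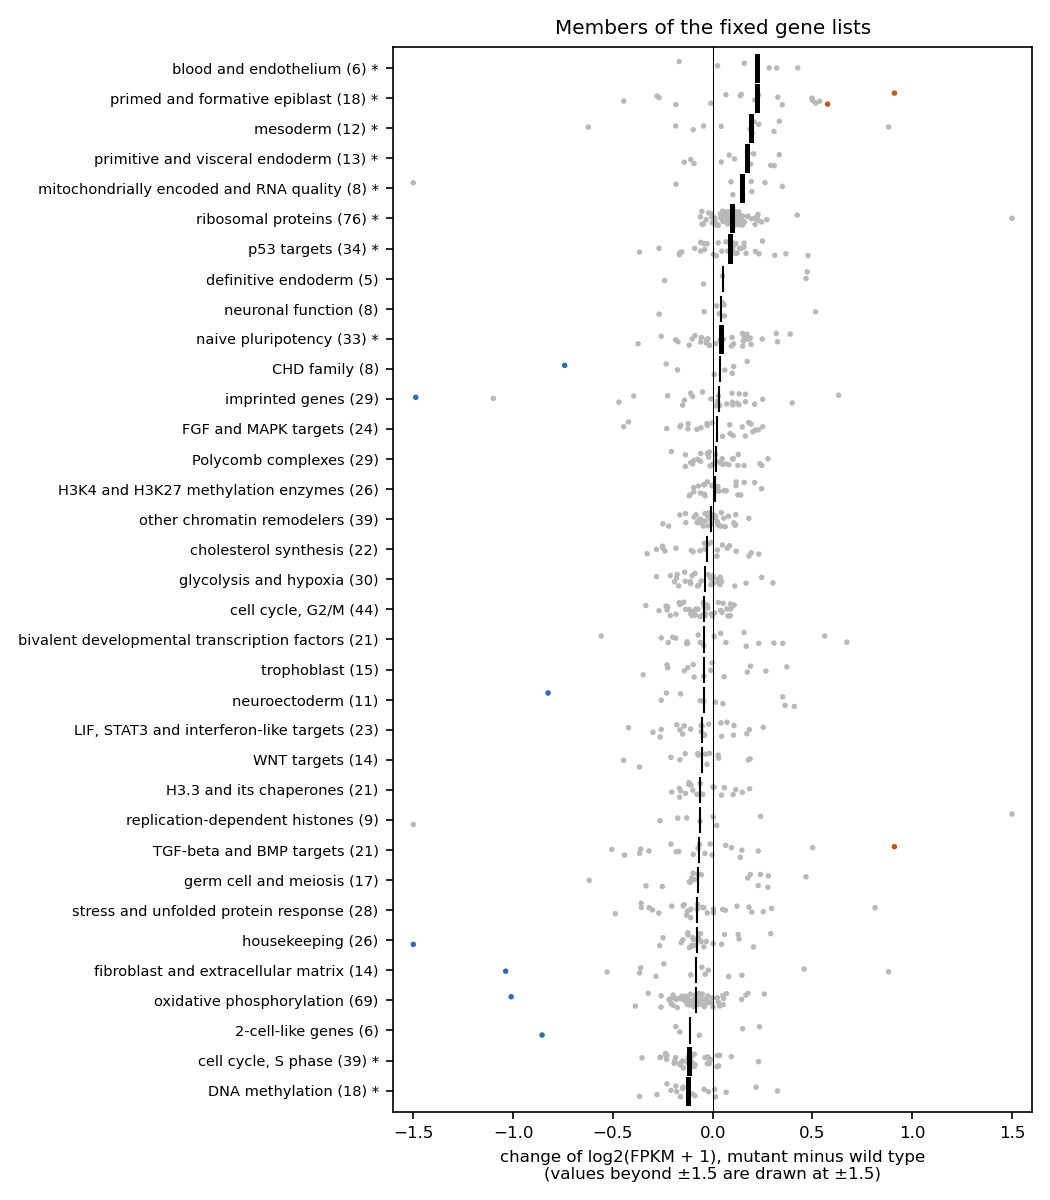
Change of log2(FPKM + 1), mutant minus wild type (x axis), of the genes kept in each of 35 lists (y axis, number of genes in brackets), with orange and blue points for genes called higher and lower, grey points for the rest, black bars for medians and values beyond the axis drawn at its edge. Thick bars and asterisks mark the 10 lists outside the central 95% of random lists matched on expression, with S phase and DNA methylation on the lower side.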

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

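The q threshold, the plain ratio, the small RNA, GC and length and shared-member settings were chosen after seeing the data. Requiring a mean FPKM of at least 5 left 50 of the 81 calls, and requiring an absolute log2 fold change of at least 1 left 28, with 4 higher and 24 lower (85.7% lower, against 64.2% of all calls). These are subsets by construction. With a mean FPKM of at least 1, 75 calls remained, and with a q of at most 0.02, 63. Chd2 stayed lower, between -0.83 (pseudocount 0.1) and -0.74 (median set to 0) in the planned settings and at -0.84 without a pseudocount. No call changed direction under quantile normalization or with the median set to 0. The 24 named called genes kept their direction in all 96 values, 16 of which moved by over 1.5 times. A pseudocount cannot reverse a direction, and the median that was set to 0 was only -0.0012. Only quantile normalization could therefore have reversed a call, so these settings are a weak check of direction. Between 9 and 11 lists lay outside the central 95% in each setting. The naive pluripotency, primed epiblast, p53, ribosomal protein and S phase lists were outside in every setting that could be run. Without a filter, the mesoderm, primitive endoderm and blood lists were inside. With a mean of at least 5 FPKM the mesoderm and blood lists kept too few genes for a percentile. The RNA quality list was inside after GC and length correction. Removing shared members put the DNA methylation list inside and left the mesoderm list too few genes. Lists inside the range in the results also came to lie outside it: the TGF-beta and BMP list with a pseudocount of 0.1 (percentile 2.03), the 2-cell-like (0.02), FGF and MAPK (99.4) and histone lists (below every random list) without a filter, the CHD family (1.91), FGF and MAPK (97.52) and fibroblast (0.05) lists with a mean of at least 5 FPKM, the H3.3 list after GC and length correction (1.57) and the bivalent list without shared members (1.6). No paired analysis was possible because the table holds 1 value per genotype and none per lot. For the same reason leaving out libraries, the variance models, camera and fry were not run, and summing rows of a symbol changed nothing since no symbol repeats. Depth is unknown and sets no limit that can be stated.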

Other observations

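Tests of admixed extraembryonic cells, of fewer fibroblast-like cells, of chromosome gain or loss, of the neighbours other than the Igsf23 trio and of transcript length alone were chosen after the result was seen, as were all genes named in this part that the rule does not take. Stag3, a meiotic cohesin subunit, fell 1.82-fold, the testis tubulin gene Tuba3a fell 2.26-fold and Rpl39l, a ribosomal protein paralog abundant in testis, fell 2.22-fold from 33.0 to 14.9 FPKM, beside Fmr1nb, Nlrp9b and Pramel6. Tuba3a and Rpl39l have close paralogs, and reads shared with these were not tested. The germ cell list fixed in advance held no call among its 17 genes kept, and its median of -0.07 lay at percentile 2.85, inside the central 95% of matched random lists.

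Usp9y fell 2.75-fold, while other Y-linked genes were uncalled in the authors' deposited table. Ddx3y was at 14.5 and 11.3 FPKM in wild type and mutant, Eif2s3y at 32.0 and 35.5 FPKM, and Uty at 5.14 and 4.96 FPKM. Odc1, the rate-limiting enzyme of polyamine synthesis, fell from 598 to 397 FPKM, Txnip from 34.3 to 19.3 FPKM, Akr1b8 from 23.9 to 10.7 FPKM and Lars2, the mitochondrial leucyl-tRNA synthetase, from 52.7 to 33.5 FPKM. Ifitm1, an interferon-induced membrane protein gene, rose from 241 to 396 FPKM.

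In the first pattern Cldn6, Cldn7, Crb3, Dsp, St14, Ap1m2, Tmem30b and Cd24a, 8 genes of epithelial cells, rose by 0.40 to 0.98 on the log2(FPKM + 1) scale, while Zeb1, a repressor of epithelial genes, fell 1.84-fold from 1.38 to 0.754 FPKM and Vim fell. These 8 were picked because they were called, and the epithelial genes Cdh1 (42.6 and 52.8 FPKM in wild type and mutant), Epcam (86.5 and 89.6 FPKM) and Esrp1 (7.72 and 9.75 FPKM) were not. Mesenchymal genes went both ways. The uncalled Fn1 (31.8 and 44.1 FPKM), Tagln (1.15 and 2.97 FPKM) and Twist1 (2.35 and 2.93 FPKM) were higher in the mutant. Of the 14 fibroblast and matrix genes kept, Vim, Fn1 and Tagln among them, 10 lay below 0 and 4 above. The primitive endoderm list lay at percentile 99.98, as admixed extraembryonic cells would give. Without the filter on low values it lay at percentile 57.17. The fibroblast list lay at percentile 0.05 among genes with a mean of at least 5 FPKM, as fewer fibroblast-like cells would give. The summed FPKM of markers with a mean under 1 FPKM changed by -1.27 (primitive endoderm, 20 genes), -0.225 (trophoblast, 12 genes) and 0.0353 (fibroblast, 19 genes). The changes to be matched were 61.0 for the 8 genes together and -81.4 for Vim. A marker raised by admixed cells could pass the limit and leave the set. In the primitive endoderm and trophoblast lists, however, no gene under 1 FPKM in wild type reached 1 FPKM in the mutant. The lack of a rise goes against admixed cells of these kinds. It does not exclude them, because these markers lie near the floor and the kept primitive endoderm genes mostly rose. The fibroblast markers cannot decide, because they summed to only 2.62 FPKM in wild type and could not fall as far as Vim. Both explanations stay open. A wider release of epithelial genes with lower Zeb1 is a candidate explanation: 41 other epithelial genes, listed before their values were seen and leaving out those already looked at, Cdh1, Epcam and Esrp1 among them, had a median change of 0.07 at percentile 98.6 of matched random lists, and at 99.1 after GC and length correction. None of the 41 was called, 27 lay above 0, Elf3, Cldn3 and Grhl2 lay below, and 10 of 35 other lists were as far out, so this stays a hypothesis, and a difference between the cell lines unrelated to Chd2 stays open as untested.

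In the second pattern, of 81 called genes, 5 pairs no more than 5 genes apart in the order of 11218 genes changed in the same direction: Igsf23, Ceacam20 and Nlrp9b fell as a trio on chromosome 7, Atp5c1 and Sfmbt2 fell on chromosome 2 (with Kin between them at 19.2 and 19.4 FPKM), and C2cd5 and Etnk1 rose on chromosome 6. Within the same distance 3 other pairs changed in opposite directions, and whether neighbours share a direction was not tested apart from their placement. A share of 0.0185 of 2000 random placements of the calls gave as many pairs, but without the trio the 2 pairs left were matched in a share of 0.406, so the excess rests on the trio and chance could account for the others. Shared reads of overlapping genes are argued against, as 100% of the pairs did not overlap in the GRCm38 annotation, and so is a whole-chromosome gain or loss, as the largest median of these chromosomes was 0.0090 in size. For the trio, an effect on a shared regulatory region and a difference between the cell lines stay open as untested.

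The third pattern concerns small shifts of many genes, with ribosomal protein genes up by a median of 0.10 and S phase genes down by 0.12. The change correlated across genes with transcript length (Spearman rho 0.18) and mean FPKM (rho -0.19), and genes are not independent replicates. Removing the trend on GC content and length left the S phase list at percentile 0.03, with a median of -0.11, and the ribosomal protein list above all random lists, with a median of 0.14. For the ribosomal protein list, transcript length alone is also argued against by the oxidative phosphorylation genes. With the longest annotated transcript of each gene, their median length was 1231 bases against 1077 (ribosomal) and 3198 (all genes kept). Yet they lay at percentile 5.17, on the other side. Part of that position goes with GC content and length, as it was 35.5 after the correction. The comparison does not bear on the S phase genes, whose median length was 3381 bases. A difference in growth or RNA quality between the cultures may give such shifts as well as the genotype could, and values for the separate lots would be needed to weigh them.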
